A study of Homo sapiens with 9 samples.

How the data were processed

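Total RNA of MDA-MB-231 recipient cells was sequenced in 9 libraries, 3 with no vesicles, 3 with vesicles of DMSO-treated donors (Cont sEV) and 3 with vesicles of donors treated with nocodazole at 100 ng/ml (TIS sEV). Per the labels' protocols, donors were treated for 72 h and then kept for 72 h in medium without exosomes, and recipients were incubated for 72 h in medium with 5% serum. The values used are gene-level TPM as deposited by the authors, with 60719 Ensembl genes in 1 table. Per the submitters' processing notes, the tools were FastQC 0.11.9, Trim Galore 0.6.6, Salmon 1.4.0 and DESeq2 1.28.0, with the build GRCh38.p13; the annotation release is not given in the sources used here. TPM keeps no read depth, so the depth per library is unknown, no counts were used, and no count model was fitted.

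Groups and replicate numbers come from the labels. Gene symbols were matched by Ensembl ID (99.58% matched) and coordinates taken from GENCODE 29 on GRCh38, which may differ from the release the authors used. Values were transformed to log2(TPM + 1), so fold changes of low genes are understated, and genes with at least 1 TPM in at least 3 of the 9 libraries were kept, 13879 in all. limma 3.58.1 in R 4.3.3 fitted all 9 libraries at once, with a variance trend on expression and two-sided moderated tests, and p-values were adjusted by Benjamini-Hochberg over all genes within a comparison at 0.05. A moderated F test compared the 3 groups. Camera, with a preset inter-gene correlation of 0.01, tested 39 of 42 gene lists, those with at least 5 tested genes; lists were also tested with an estimated correlation and with fry, whose directional p asks whether a list's genes move, on balance, one way. A list is said to move where camera, which ranks its genes against all others, passed at 0.05. Fry makes no such comparison, so a shift of scale over all genes can help a list pass it. Adjusted p-values of lists are over the 39 lists. Median 95% confidence intervals of a fold change extended 0.13 on the log2 scale to each side for genes with a mean of at least 5 TPM. The mitochondrial share was compared by exact permutation tests. Figures were drawn with matplotlib 3.10.9.

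The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, per comparison, up to 10 genes with the highest and up to 10 with the lowest fold change among those that passed, had a mean of at least 5 TPM and had groups that did not overlap, filled to 5 per direction by smallest p; up to 4 genes of smallest p per list; and a fixed set of senescence, mitosis and reference genes. CST2 and PRSS3 were added after their values were seen, as were the k-mer comparisons of genes with similar relatives, the removal of GC and length trends, and the removal of both libraries of lowest weight. The removal of GC and length trends also takes out each library's mean offset over genes, so it rescales the libraries as well.

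The steps were tested on simulated data with 13879 genes and 200 changed genes per draw. Genes were drawn independently of each other, with the same spread in all groups. In TIS sEV vs Cont sEV 841 genes were called over 5 draws, which makes the adjusted threshold easier to pass than in the real data. The shares recovered may therefore overstate what the real tests find. For TIS sEV vs Cont sEV, 41.5% of genes changed by 0.25 on the log2 scale, 90.4% of those changed by 0.5 and 99.7% of those changed by 1 were recovered, with 6.3% false calls. For TIS sEV vs No sEV these shares were 44.5%, 88.7% and 99.4%, with 5% false calls. No change was simulated between Cont sEV and No sEV, where 0 genes were called, so recovery in that comparison was not measured. Alternatives were other pseudocounts and filters, median-of-ratios and quantile scaling, leaving out mitochondrially encoded genes, the replicate number as a block, a constant prior variance, library weights, only the libraries compared, a minimum fold of 1.5, and leaving out each library. All 9 columns of the table were used. Some genes and 1 gene list that entered the tests and the counts are not reported here.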

Results

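RNA from MDA-MB-231 cells, a human triple-negative breast cancer line, was sequenced after 72 h with or without small extracellular vesicles (sEV) from donor cultures of the same line. The 9 libraries form 3 groups of 3. No sEV cells received no vesicles, Cont sEV cells received vesicles of donors treated with the solvent DMSO, and TIS sEV cells received vesicles of donors made senescent with the microtubule inhibitor nocodazole (therapy-induced senescence). Transcript levels are gene-level TPM (relative transcript abundances), so each library sums to 1000000 and its read depth is unknown. Between 21292 and 21975 genes per library had a value above 0, and 13879 genes passed the filter of at least 1 TPM in at least 3 libraries. The libraries were close to each other: Pearson's r over genes was 0.991 to 0.994 within groups and 0.992 to 0.994 between groups, and the first principal component held 16.3% of the variance without separating the groups. On the second component (14.6%), the 3 Cont sEV libraries lay from -8.54 to -4.41, below the other 6, which lay from -2.47 to 18.2 with No sEV and TIS sEV overlapping. TIS sEV replicate 3 had the value of 18.2 there, and the SD of its log2 differences from other libraries, over 3386 genes with a mean of at least 50 TPM, was 0.131 to 0.153, against 0.0777 to 0.132 in pairs of the others. No 2 libraries were identical. Because the labels do not say whether replicates were separate cultures, the p-values measure only the spread between these samples, which may be technical.

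The comparison of TIS sEV with Cont sEV asks whether vesicles of nocodazole-treated, senescent donors act differently from those of DMSO-treated donors. Only recipients were sequenced, so donor senescence was not measured here. Its effect cannot be told apart from other effects of the nocodazole treatment. The genes of smallest adjusted p were lower with TIS sEV. PRSS2, which encodes a trypsinogen, was at 51.4 ± 1.46 TPM (SD, n = 3) with TIS sEV against 75.2 ± 0.672 with Cont sEV. CST1 and CST4, which encode secreted cystatins that inhibit cysteine proteases, fell as well: CST1 was at 828 ± 20.02 against 1146 ± 13.2 TPM, and CST4 at 217 ± 6.57 against 299 ± 11.7 TPM. Among the genes that rose were the tissue factor gene F3, at 348 ± 10.7 against 296 ± 4.19 TPM, and ANKRD1, at 706 ± 7.35 against 621 ± 11.4 TPM. All of these differences were small, none reaching 1.5-fold.

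In limma's moderated test with Benjamini-Hochberg adjustment, 13 genes differed between TIS sEV and Cont sEV, 6 higher and 7 lower, with absolute log2 fold changes from 0.18 to 0.54 on the log2(TPM + 1) scale. The log2 fold change of PRSS2 was -0.54 (SE 0.03, adjusted p = 0.000179). That of CST1 was -0.47 (SE 0.03, adjusted p = 0.000179), and that of CST4 was -0.46 (SE 0.04, adjusted p = 0.00577). The other 4 genes that fell were NDRG1, a hypoxia-responsive gene (-0.36, adjusted p = 0.0343), and the organic anion transporter gene SLCO4A1 (-0.30, adjusted p = 0.0227), besides the macrophage growth factor gene CSF1 (-0.27, adjusted p = 0.0252) and MARCKSL1 (-0.26, adjusted p = 0.0343). For NDRG1 and PRSS2 the level with Cont sEV was also above that with No sEV, without passing the test. With 1 library left out, those log2 fold changes were 0.23 to 0.31 for NDRG1 and 0.27 to 0.30 for PRSS2. Among the genes that rose were KRTAP2-3, a keratin-associated protein gene (+0.51, adjusted p = 0.0343), the pro-apoptotic gene PAWR (+0.30, adjusted p = 0.0387) and the BMP antagonist gene NOG (+0.28, adjusted p = 0.0343). So did F3 (+0.23, adjusted p = 0.0252), CCDC124 (+0.22, adjusted p = 0.0252) and ANKRD1 (+0.18, adjusted p = 0.0343). In each of the 13, the 3 TIS sEV libraries lay apart from the 3 Cont sEV libraries. Genes of very small p tend to be separated, so this adds no support to the calls. Separation of this kind was found for 15.4% of tested genes, where chance gives 10%. A shift of scale between the groups can raise that share, and the median log2 fold change over all genes was 0.02.

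**Figure D1:**
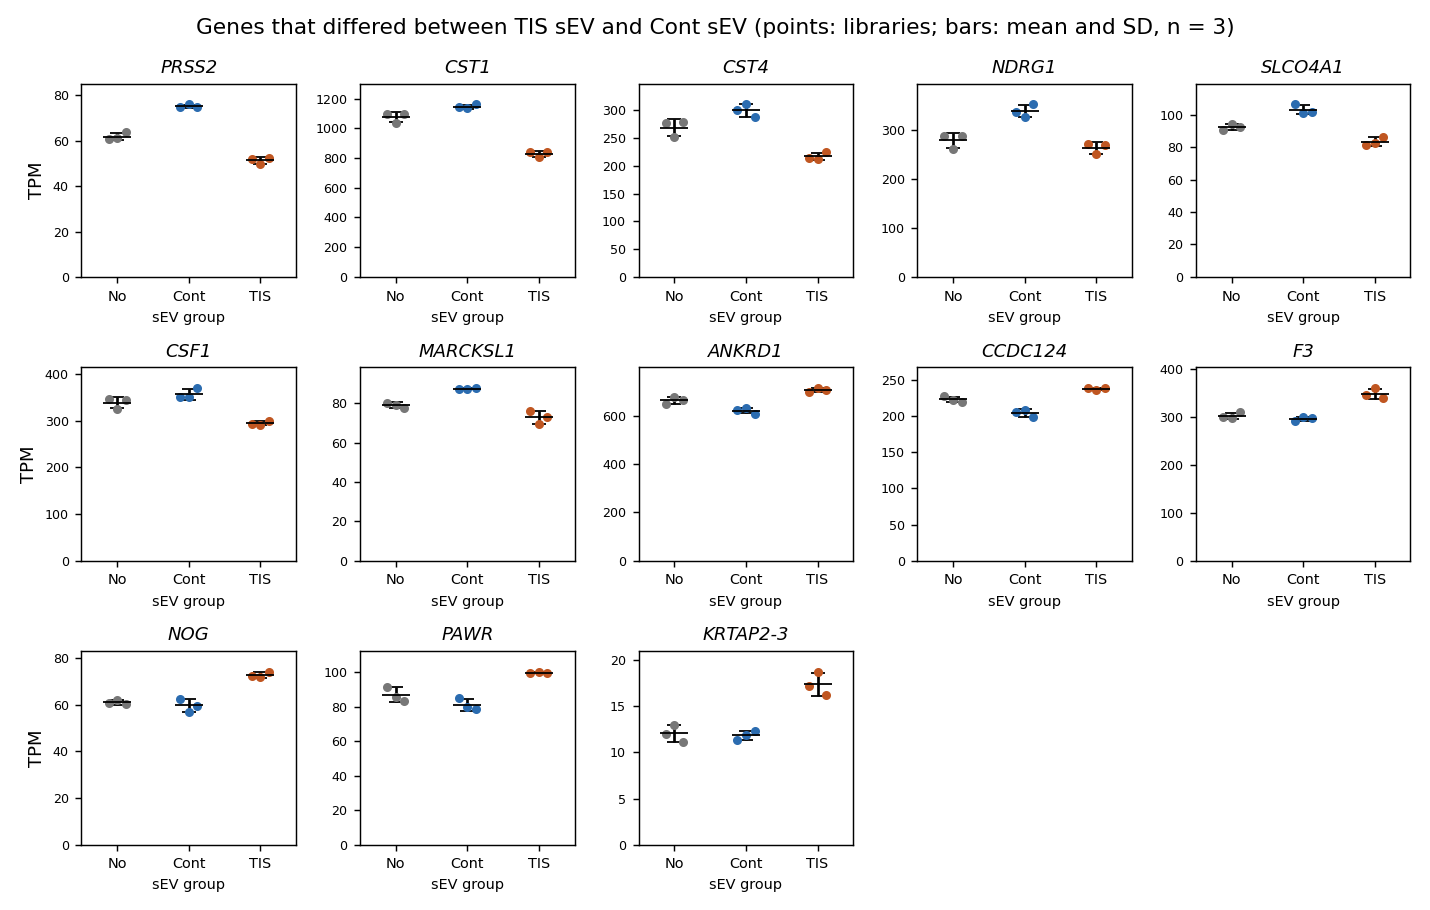
TPM (vertical axis, from 0) of the 13 genes that differed between TIS sEV and Cont sEV, by sEV group, with 1 point per library and bars for the mean and SD of 3 libraries. The TIS sEV points of CST1, around 828 TPM, lie below those of both other groups, and those of KRTAP2-3, around 17.4 TPM, lie above them.

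On GRCh38, PRSS2 (ENSG00000275896.6) spans chromosome 7 from 142760398 to 142774564. CST1 (ENSG00000170373.8) spans chromosome 20 from 23747553 to 23751268, and CST4 (ENSG00000101441.4) lies near it from 23685640 to 23689040. NDRG1 (ENSG00000104419.17) spans chromosome 8 from 133237171 to 133302022, KRTAP2-3 (ENSG00000212724.3) chromosome 17 from 41059240 to 41060114, and F3 (ENSG00000117525.14) chromosome 1 from 94529225 to 94541800. All are annotated as protein-coding genes. PRSS2, the cystatin genes and KRTAP2-3 have relatives of similar sequence, among which reads can be shared, so their separate TPM values carry that uncertainty. Of the 31-mers of each gene's transcripts, 14.3% of those of PRSS2 also occur in PRSS1, 34.6% of those of CST1 in CST4 and 43.1% of those of KRTAP2-3 in KRTAP2-4. PRSS3, a relative of PRSS2, had a log2 fold change of -0.07 (adjusted p = 0.663). CST2, another cystatin gene, singled out after its values were seen, had a log2 fold change of -0.34 (adjusted p = 0.0737).

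Leaving out single libraries left PRSS2 and CST1 past the threshold each time. The count of 13 fell to 2 without Cont sEV replicate 2 or TIS sEV replicate 1, and to 3 without No sEV replicate 3 or Cont sEV replicate 3. It fell to 4 without TIS sEV replicate 2, of which 3 were among the 13. Without TIS sEV replicate 3 it was 6, of which 5 were among the 13, and without No sEV replicate 1 it was 8. Without Cont sEV replicate 1 there were 10 calls, 5 of them among the 13, and without No sEV replicate 2 there were 13, of which 10 were shared. With libraries rescaled by median ratios the calls were 3 higher and 11 lower, and after quantile normalization 6 higher and 11 lower.

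Cell-cycle transcripts were slightly higher with TIS sEV than with Cont sEV. Of 40 G1/S and DNA replication genes, 34 had a higher mean, with a median log2 fold change of 0.08, against 0.02 over all genes (camera, adjusted p = 0.000273; adjusted p = 0.102 with an estimated correlation). The members of smallest p were PCNA at 179 ± 3.87 against 167 ± 2.82 TPM and E2F1 at 34.1 ± 0.394 against 30.9 ± 0.607. FEN1 was at 125 ± 4.27 against 114 ± 1.18 and MCM3 at 154 ± 1.63 against 143 ± 4.76. None of these single genes passed over all genes or adjusted over the list alone. Of 35 G2/M and mitosis genes, 30 had a higher mean, with a median of 0.06 (adjusted p = 0.000273; adjusted p = 0.318 with an estimated correlation). Both lists still passed at smaller medians after quantile normalization (0.0544 for G1/S and 0.0367 for G2/M) and with both lowest-weight libraries left out (0.0550 and 0.0403), as did G1/S with GC and length trends removed (0.0548). In the G2/M list 0 genes passed over all genes and 2 passed adjusted over the list alone, UBE2C (245 ± 0.268 against 220 ± 1.71 TPM) and CDC25C (18.7 ± 0.575 against 15.5 ± 0.771 TPM). Neither list moved in TIS sEV vs No sEV (camera, adjusted p = 0.664 for G1/S and 0.120 for G2/M).

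The YAP/TAZ target list moved up, with 17 of 23 genes higher and a median log2 fold change of 0.06 (camera, adjusted p = 0.000333; adjusted p = 0.503 with an estimated correlation), or 0.03 without Cont sEV replicate 2 (adjusted p = 0.0316). It also passed at 0.0395 after median-of-ratios rescaling, 0.0362 after quantile normalization and 0.0344 without both lowest-weight libraries. F3 and ANKRD1 passed over all genes, and 5 genes passed adjusted over the list alone, among them CCN1 (1740 ± 41.6 against 1559 ± 30.7 TPM) and GADD45A (86.0 ± 3.28 against 73.7 ± 2.73 TPM). The immediate early gene list moved up with 18 of 25 genes higher and a median of 0.06 (adjusted p = 0.00226; adjusted p = 0.465 with an estimated correlation), and passed at 0.0415 after median-of-ratios rescaling and 0.0345 with GC and length trends removed. It held 0 genes that passed over all genes and 7 adjusted over the list alone, among them JUN (113 ± 4.40 against 96.6 ± 1.79 TPM) and JUND (149 ± 14.1 against 114 ± 1.22 TPM). The cell migration and cytoskeleton list moved up (27 of 32 genes higher, median 0.04, adjusted p = 0.0172; adjusted p = 0.621 with an estimated correlation), with no member passing over all genes or adjusted over the list alone. The migration list no longer passed without Cont sEV replicate 2 (median 0.02, adjusted p = 0.279), TIS sEV replicate 1 (median 0.0453, adjusted p = 0.0718) or TIS sEV replicate 3 (median 0.0360, adjusted p = 0.183). Nor did it pass after median-of-ratios rescaling (median 0.02, adjusted p = 0.180), with mitochondrially encoded genes left out (median 0.03, adjusted p = 0.0622) or with GC and length trends removed (median 0.03, adjusted p = 0.0976). The senescence-associated secretory factor list did not move between TIS sEV and Cont sEV (20 of 33 higher, median 0.004, adjusted p = 0.703), with 0 genes passing over all genes and 3 adjusted over the list alone, CXCL1 and CSF2 among them. In TIS sEV vs No sEV the YAP/TAZ and migration lists did not move (camera, adjusted p = 0.120 and 0.272).

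All 13 mRNAs encoded in the mitochondrial genome were lower with TIS sEV than with Cont sEV, with a median log2 fold change of -0.45 (camera, adjusted p = 1.37e-19; adjusted p = 0.318 with an estimated correlation). None passed over all genes and 11 passed adjusted over the list alone. MT-CYB was at 300 ± 28.8 TPM against 454 ± 75.1 TPM, and MT-CO3 was at 1898 ± 149 against 2779 ± 403 TPM. These mRNAs made up 1.86 ± 0.195% of the summed TPM with TIS sEV, 2.54 ± 0.362% with Cont sEV and 2.22 ± 0.186% with No sEV (n = 3 each). The TIS sEV and Cont sEV values did not overlap (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 can give). The share overlapped between TIS sEV and No sEV (exact permutation test, p = 0.2) and between Cont sEV and No sEV (exact permutation test, p = 0.3). Without Cont sEV replicate 1, MT-CYB, MT-ND3, MT-CO3 and MT-ATP6 passed over all genes, MT-CYB with a log2 fold change of -0.73 (adjusted p = 0.0282).

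The glycolysis and hypoxia list moved down, with 25 of 35 genes lower and a median log2 fold change of -0.03 (camera, adjusted p = 0.000273; adjusted p = 0.465 with an estimated correlation), or -0.0538 after median-of-ratios rescaling and -0.0531 with GC and length trends removed. NDRG1 passed over all genes, and NDRG1, P4HA1 (71.8 ± 0.721 against 77.9 ± 0.930 TPM) and EGLN3 (4.93 ± 0.841 against 7.17 ± 0.616 TPM) adjusted over the list alone. The cytosolic ribosomal protein list moved down (48 of 75 lower, median -0.01, adjusted p = 0.0145; adjusted p = 0.658 with an estimated correlation). It moved up after quantile normalization, and did not pass without Cont sEV replicate 2 (median -0.00359, adjusted p = 0.889) or TIS sEV replicate 2 (median -0.00564, adjusted p = 0.578), with no filter on low values (adjusted p = 0.103) or with library weights (adjusted p = 0.188). Its median was -0.0223 without Cont sEV replicate 1 and -0.0230 without TIS sEV replicate 1. The list passed at larger medians after median-of-ratios rescaling (-0.0354), with mitochondrially encoded genes left out (-0.0257) and with GC and length trends removed (-0.0327). In total 9 of 39 lists moved, 6 up and 3 down, and 0 did with an estimated correlation. The glycolysis and hypoxia list did not move between TIS sEV and No sEV (20 of 35 higher, median 0.005, camera, adjusted p = 0.390).

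**Figure D2:**
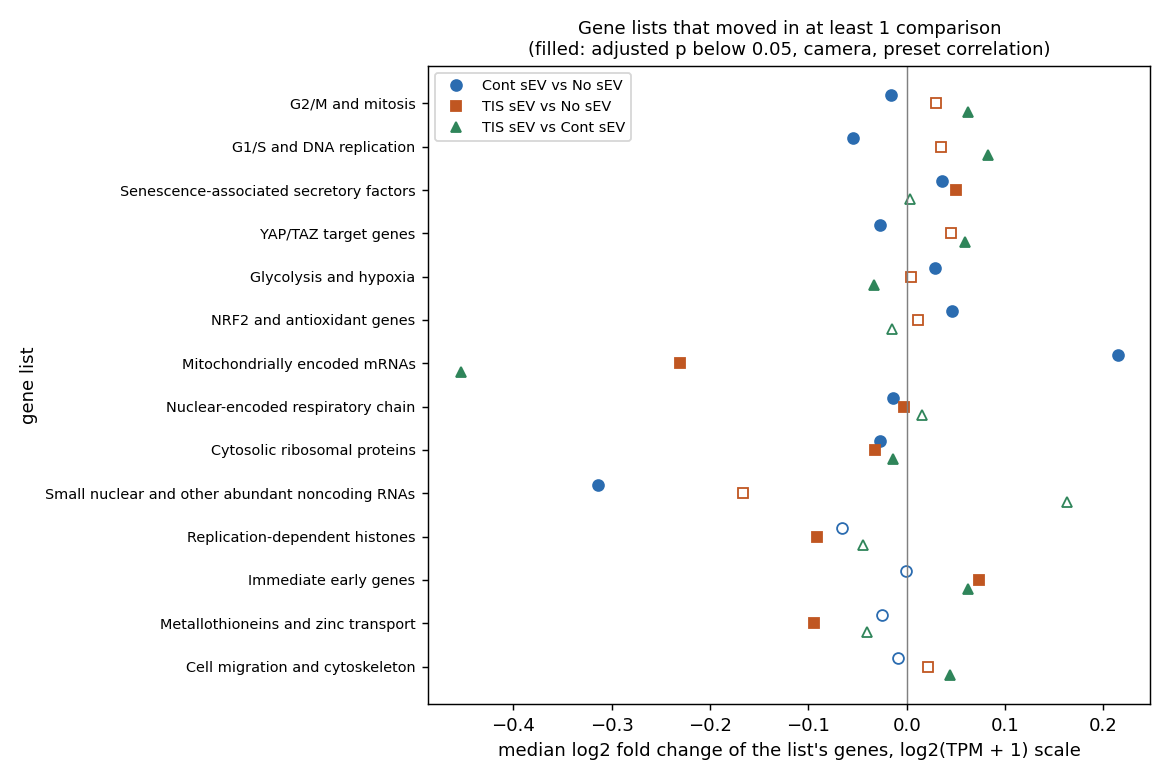
Median log2 fold change (horizontal axis, log2(TPM + 1) scale) of gene lists that moved in at least 1 comparison. Colours and shapes mark the comparison, and filled symbols an adjusted p below 0.05 in camera with its preset correlation. The mitochondrially encoded list spans from -0.45 in TIS sEV vs Cont sEV to 0.21 in Cont sEV vs No sEV.

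The comparison of TIS sEV with No sEV asks what vesicles of nocodazole-treated, senescent donors change relative to none. CST1 was the gene that fell, from 1077 ± 34.5 TPM (SD, n = 3) with No sEV to 828 ± 20.02 TPM with TIS sEV. Transcripts of the secretory factors that senescent cells release, such as chemokines and interleukin 1, were slightly higher as a group, with a median log2 fold change of 0.05 against 0.03 over all genes (camera, adjusted p = 8.76e-05; adjusted p = 0.0807 with an estimated correlation). The median of the list was 0.02 after median-of-ratios rescaling, which brought that over all genes to 0.00125. CXCL1 was at 677 ± 11.1 against 596 ± 19.1 TPM and IL1B at 268 ± 4.73 against 244 ± 6.46 TPM.

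The log2 fold change of CST1 was -0.38 (SE 0.03, limma, adjusted p = 0.00175), and 0 other genes passed, while 1106 had an unadjusted p under 0.05 where 694 would by chance. Of the 1106, 879 were higher and 227 lower, where the median over all genes was 0.03 and 0.00125 after median-of-ratios rescaling. The count thus does not separate changed genes from a shift of scale between libraries. The next genes by p did not pass and are given as values. KRTAP2-3 was at 17.4 ± 1.24 against 12.1 ± 0.911 TPM (adjusted p = 0.130) and F3 at 348 ± 10.7 against 302 ± 6.55 (adjusted p = 0.130). NOG was at 72.6 ± 1.20 against 60.9 ± 0.986 (adjusted p = 0.137) and TIPARP at 71.6 ± 0.345 against 63.0 ± 0.228 (adjusted p = 0.136). PLAT, the tissue plasminogen activator gene, was at 907 ± 9.002 against 804 ± 30.96 (adjusted p = 0.172). Lower values were found for PRSS2 (51.4 ± 1.46 against 61.8 ± 1.63 TPM, adjusted p = 0.130) and CST4 (217 ± 6.57 against 268 ± 15.002, adjusted p = 0.130). The same held for CSF1 (295 ± 4.83 against 339 ± 12.1, adjusted p = 0.179) and HSD17B12 (116 ± 0.506 against 129 ± 2.28, adjusted p = 0.2504). CST1 passed without each library in turn. Leaving out Cont sEV replicate 2, TIS sEV replicate 2 or TIS sEV replicate 3 raised the count to 2.

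The senescence-associated secretory factor list moved up against No sEV, with 28 of 33 genes higher (camera, adjusted p = 8.76e-05; adjusted p = 0.0807 with an estimated correlation). It passed at a median of 0.0179 after median-of-ratios rescaling (adjusted p = 0.0076), 0.0297 after quantile normalization and 0.0283 with GC and length trends removed. Over all genes 0 members passed, and 11 passed adjusted over the list alone, among them CXCL1, IL1B and CSF2 (389 ± 10.1 against 353 ± 4.33 TPM). The immediate early gene list moved up with 22 of 25 genes higher (median 0.07, adjusted p = 0.00594; adjusted p = 0.340 with an estimated correlation), with FOSL1 (442 ± 9.61 against 403 ± 7.90 TPM) the member adjusted over the list alone. The list did not pass without No sEV replicate 2, where its median stayed at 0.07 (adjusted p = 0.0697). Nor did it at smaller medians after median-of-ratios rescaling (0.0409, adjusted p = 0.0685), with GC and length trends removed (0.0307, adjusted p = 0.0810) or without both lowest-weight libraries (0.0576, adjusted p = 0.0592), while it passed at 0.0488 after quantile normalization. The interferon response list did not move in camera (adjusted p = 0.0824), with 30 of 35 genes higher, 0 passing over all genes and IFI44, OASL and IFIT3 passing adjusted over the list alone. It did pass fry's directional test (adjusted p = 0.0145). ISG15 was at 317 ± 8.82 against 290 ± 14.96 TPM. The epithelial junction and keratin list (17 of 18 higher) likewise passed in fry (adjusted p = 0.0353) and not in camera (adjusted p = 0.0824). Fry does not set a list against other genes and was not run on rescaled values. The median of 0.03 over all genes in TIS sEV vs No sEV can therefore add to both of these passes.

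Lists that moved down against No sEV were cytosolic ribosomal proteins (58 of 75 lower, median -0.03, camera, adjusted p = 1.69e-14; adjusted p = 0.318 with an estimated correlation), for example RPS13 at 1503 ± 34.1 against 1617 ± 43.6 TPM. Mitochondrially encoded mRNAs moved down as well (13 of 13 lower, median -0.23, adjusted p = 1.55e-13; adjusted p = 0.321 with an estimated correlation). The ribosomal protein list did not pass after quantile normalization (median -0.0045, adjusted p = 0.722). It passed at a median of -0.02 without No sEV replicate 1, -0.0658 after median-of-ratios rescaling and -0.0615 with GC and length trends removed. The metallothionein and zinc transport list moved down (4 of 6 lower, median -0.09, adjusted p = 0.000595; adjusted p = 0.193 with an estimated correlation), with MT1X at 701 ± 13.96 against 765 ± 11.2 TPM. So did replication-dependent histones (13 of 19 lower, median -0.09, adjusted p = 0.00594; adjusted p = 0.193 with an estimated correlation), which did not pass without No sEV replicate 1 (median -0.04, adjusted p = 0.0923). The histone list did not pass either at larger medians after median-of-ratios rescaling (-0.12, adjusted p = 0.0947), quantile normalization (-0.13, adjusted p = 0.0706) or removal of GC and length trends (-0.12, adjusted p = 0.0931), and passed at -0.03 with no filter on low values (adjusted p = 0.0243). Nuclear-encoded respiratory chain genes ranked below other genes in camera (adjusted p = 0.0277; adjusted p = 0.407 with an estimated correlation). Their own median was -0.003, with 29 of 52 lower, against 0.03 over all genes, and fry's directional test did not pass (adjusted p = 0.793). The camera call was lost without No sEV replicate 1 (median -0.00126, adjusted p = 0.182), No sEV replicate 2 (median 0.00900, adjusted p = 0.184) or TIS sEV replicate 2 (median 0.00156, adjusted p = 0.233), after quantile normalization (median -0.0114, adjusted p = 0.207), with no filter on low values (adjusted p = 0.150) and with library weights (adjusted p = 0.0654). It held at a median of -0.02 without No sEV replicate 3, -0.01 without TIS sEV replicate 1 and 0.0028 without TIS sEV replicate 3. It also held at -0.0361 after median-of-ratios rescaling, -0.0324 with GC and length trends removed and -0.00926 with mitochondrially encoded genes left out. In these 5 lists 0 genes passed over all genes, and 1 metallothionein (MT1X) and 2 mitochondrial mRNAs passed adjusted over the list alone.

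The comparison of Cont sEV with No sEV asks what vesicles of DMSO-treated donors do by themselves. No single gene passed the test. As groups, secretory factor transcripts were slightly higher and DNA replication transcripts slightly lower with Cont sEV, for example MMP3 at 57.1 ± 1.47 against 50.6 ± 1.11 TPM (SD, n = 3) and PCNA at 167 ± 2.82 against 174 ± 2.38 TPM. The nearest single genes were PRSS2, at 75.2 ± 0.672 against 61.8 ± 1.63 TPM, and KISS1, a metastasis suppressor gene, at 334 ± 13.9 against 414 ± 3.31 TPM.

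In limma 0 genes passed and 837 had an unadjusted p under 0.05, 490 higher and 347 lower, where 694 would by chance. The smallest adjusted p was 0.0791, for PRSS2 and KISS1. Without Cont sEV replicate 2, 1 gene passed. Other values of small p were NDRG1 at 338 ± 12.8 against 278 ± 15.6 TPM (adjusted p = 0.448), PTGS2, which encodes cyclooxygenase 2, at 161 ± 3.70 against 142 ± 4.03 (adjusted p = 0.448), and SOCS2 at 20.4 ± 2.09 against 26.3 ± 0.272 (adjusted p = 0.610).

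The secretory factor list moved up with 28 of 33 genes higher (median log2 fold change 0.04, against 0.01 over all genes, camera, adjusted p = 6.67e-05; adjusted p = 0.0391 with an estimated correlation). The G1/S and DNA replication list moved down with 33 of 40 genes lower (median -0.05, adjusted p = 6.67e-05; adjusted p = 0.0391 with an estimated correlation). No member of either passed over all genes or adjusted over the list alone. Of the other 8 lists that moved, 3 went up. Mitochondrially encoded mRNAs moved up (13 of 13 higher, median 0.21, adjusted p = 6.58e-05; adjusted p = 0.598 with an estimated correlation), as did glycolysis and hypoxia (30 of 35 higher, median 0.03, adjusted p = 0.00153; adjusted p = 0.576 with an estimated correlation). So did NRF2 and antioxidant genes (19 of 25 higher, median 0.05, adjusted p = 0.0292; adjusted p = 0.576 with an estimated correlation). The other 5 went down. They were cytosolic ribosomal proteins (49 of 75 lower, adjusted p = 1.82e-05; adjusted p = 0.598 with an estimated correlation) and YAP/TAZ targets (13 of 23 lower, adjusted p = 0.00532; adjusted p = 0.598 with an estimated correlation). G2/M and mitosis moved down too (23 of 35 lower, adjusted p = 0.0103; adjusted p = 0.576 with an estimated correlation), as did the nuclear-encoded respiratory chain (33 of 52 lower, adjusted p = 0.0137; adjusted p = 0.576 with an estimated correlation). Small nuclear and other abundant noncoding RNAs also moved down (8 of 11 lower, adjusted p = 0.0241; adjusted p = 0.598 with an estimated correlation). In these 8 lists 0 genes passed over all genes and 1, NDRG1, passed adjusted over the list alone.

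Each of these 8 lists lost its call with at least 1 of the libraries left out. Some medians stayed near their size when the call was lost. That of the NRF2 list, 0.0460 with all libraries, was then 0.0419 to 0.0551. The glycolysis median, 0.0292 with all libraries, was 0.0268 without No sEV replicate 2. Without Cont sEV replicate 2 the mitochondrial, YAP/TAZ, G2/M and NRF2 lists did not pass (adjusted p = 0.150, 0.171, 0.0893 and 0.0893). Without Cont sEV replicate 1 the ribosomal protein, respiratory chain, noncoding RNA and NRF2 lists did not (adjusted p = 0.0721, 0.137, 0.223 and 0.0721). Without Cont sEV replicate 3 the respiratory chain, noncoding RNA and NRF2 lists did not pass (adjusted p = 0.0771, 0.146 and 0.0540). Nor, without No sEV replicate 1, did the respiratory chain and noncoding RNA lists (adjusted p = 0.186 and 0.367). Without No sEV replicate 2 this held for the glycolysis, respiratory chain and NRF2 lists (adjusted p = 0.112, 0.177 and 0.123), and without No sEV replicate 3 the YAP/TAZ and noncoding RNA lists (adjusted p = 0.0987 and 0.0509). After median-of-ratios rescaling the NRF2 list (median 0.03) and the noncoding RNA list (median -0.32) did not pass (adjusted p = 0.0754 for both). Nor did they with no filter (medians 0.04 and -0.27, adjusted p = 0.0599 and 0.0993) or TPM of at least 5 in at least 3 libraries (medians 0.04 and -0.31, adjusted p = 0.0798 and 0.0565). After quantile normalization the noncoding RNA list (median -0.33, adjusted p = 0.0756) and the respiratory chain list (median -0.01, adjusted p = 0.357) did not pass, nor did the NRF2 list with GC and length trends removed (median 0.03, adjusted p = 0.0946). The number of lists that moved was 6 without Cont sEV replicate 1.

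Medians of these lists also changed in size by over 1.5 times with 1 library left out. The mitochondrial median, 0.21, was 0.33 without Cont sEV replicate 1 and 0.12 without Cont sEV replicate 2. That of ribosomal proteins, -0.0270, was -0.0173 without No sEV replicate 2, -0.0179 without Cont sEV replicate 3 and -0.0438 without No sEV replicate 3. For YAP/TAZ targets it was -0.0271, against -0.0104 without Cont sEV replicate 2 and -0.0166 without No sEV replicate 3. For G2/M and mitosis it was -0.0156, against -0.0372 without Cont sEV replicate 1, -0.0316 without No sEV replicate 2 and -0.0246 without Cont sEV replicate 3, and -0.00907 without Cont sEV replicate 2 and -0.00821 without No sEV replicate 3. For the respiratory chain it was -0.0140, against -0.00601 without No sEV replicate 2 and -0.0260 without No sEV replicate 3. For the noncoding RNAs it was -0.31, against -0.21 without No sEV replicate 1, -0.04 without Cont sEV replicate 1, -0.53 without No sEV replicate 2 and -0.58 without Cont sEV replicate 2. After median-of-ratios rescaling the medians of glycolysis, G2/M and the respiratory chain were 0.0176, -0.0272 and -0.0258, and with GC and length trends removed 0.0151, -0.0287 and -0.0299, with ribosomal proteins at -0.0425. With mitochondrially encoded genes left out those of G2/M and the respiratory chain were -0.0102 and -0.00855. Under these rescalings and removals, each list passed at the median given.

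**Figure D3:**
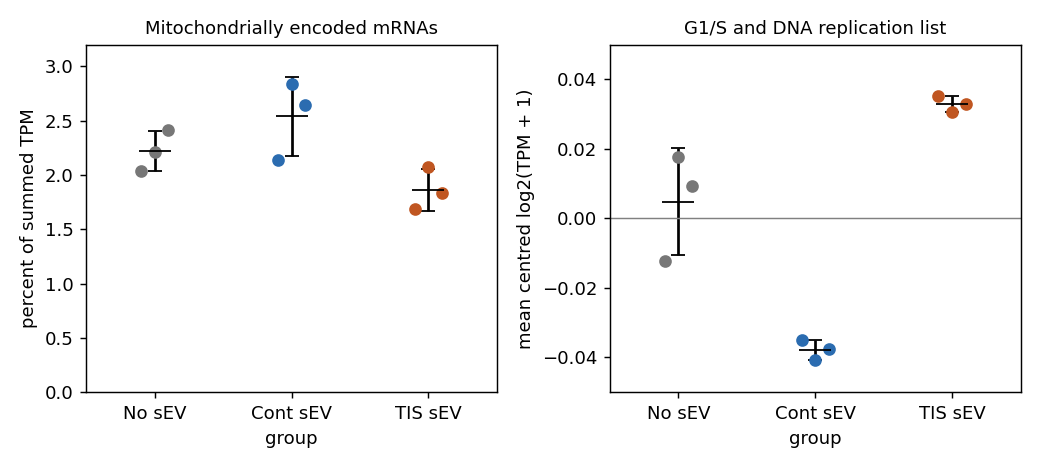
Left, mitochondrially encoded mRNAs as a percent of summed TPM, and right, the mean of the G1/S and DNA replication list after centring each gene's log2(TPM + 1) over the 9 libraries, by group, with 1 point per library and bars for mean and SD. The mitochondrial share is 1.86% with TIS sEV and 2.54% with Cont sEV.

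Across the 3 groups, limma's F test called 3 genes, CST1 (adjusted p = 0.000525), PRSS2 (adjusted p = 0.000709) and CST4 (adjusted p = 0.0193), with 1210 genes at an unadjusted p under 0.05. The comparisons share libraries, so chance ties them to each other. TIS sEV vs No sEV and TIS sEV vs Cont sEV both called CST1, lower in each. Independent lists would share 0.000504 genes and simulated unchanged groups shared 0. Neither value judges this overlap, because the comparisons share the TIS sEV libraries and unchanged groups give few calls to share. The overlap was 2 genes without TIS sEV replicate 2 or TIS sEV replicate 3. Over 10458 genes the correlation across genes of their log2 fold changes was 0.584, against 0.495 in simulated unchanged groups. The covariance was 0.00554 against 0.00408 (SD over draws 0.000674), and genes are not independent replicates. The simulation gave all groups the same spread, while log2 differences between libraries had SDs up to 0.151 within TIS sEV, 0.0941 within Cont sEV and 0.0881 within No sEV. It therefore cannot tell a shared effect from a wider spread of the shared group. For the 2 comparisons against No sEV the correlation was 0.382 (simulated 0.502) and the covariance 0.00319 (simulated 0.00416). For the 2 that share Cont sEV the correlation was -0.53 (simulated -0.50) and the covariance -0.00477 (simulated -0.00414). The 3 libraries of a group cannot be split into 2 sets of at least 2, so part of any excess may come from the shared libraries.

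Single genes of senescence, mitosis and drug response fixed beforehand differed little. As a list, cyclin-dependent kinase inhibitors and senescence regulators had 16 of 17 genes higher in TIS sEV vs No sEV, with a median of 0.0552. The list did not move in camera (adjusted p = 0.0563, or 0.321 with an estimated correlation) but passed fry's directional test (adjusted p = 0.0493). The median over all genes in that comparison was 0.0320, a shift that can help a list pass fry. In that comparison 0 genes of the list passed over all genes or adjusted over the list alone. CDKN1A, LMNB1, MKI67, CCNB1, IL6, CXCL8, TUBB, TUBA1B, GAPDH and ACTB had absolute log2 fold changes of at most 0.09 in Cont sEV vs No sEV, 0.11 in TIS sEV vs No sEV and 0.10 in TIS sEV vs Cont sEV, and none passed the test. The limit in Cont sEV vs No sEV was 0.19 without Cont sEV replicate 2. CDKN2A and CDKN2B were listed at 0 in all 9 libraries, and the drug efflux pump gene ABCB1 reached at most 0.162 TPM. The tubulin list did not move in any comparison (adjusted p = 0.703 in TIS sEV vs Cont sEV); 0 of its 13 genes passed over all genes there, and TUBB6 (257 ± 2.07 against 239 ± 7.10 TPM) and TUBA1A (203 ± 6.29 against 219 ± 0.860 TPM) passed adjusted over the list alone in opposite directions. Luminal epithelial and endothelial marker lists did not move (adjusted p = 0.549 and 0.229 in TIS sEV vs Cont sEV). There 0 of their genes passed over all genes, and adjusted over the list alone AGR2 (12.1 ± 1.53 against 14.8 ± 0.638 TPM), SPDEF (52.5 ± 1.35 against 57.2 ± 0.697 TPM) and the endothelial PECAM1 (1.45 ± 0.111 against 2.07 ± 0.0764 TPM) passed. In TIS sEV vs No sEV AGR2 passed adjusted over the list alone, at 12.1 ± 1.53 against 15.3 ± 0.287 TPM, and 0 genes of these lists over all genes. Fibroblast, leukocyte, and red cell and liver lists had too few tested genes, 3, 3 and 1, for the test.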

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

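The GC and length correction and the removal of both lowest-weight libraries were chosen after seeing the data. Of 2323 values of named genes under the alternatives, 2176 kept their direction and side of the threshold, 131 lost and 16 gained significance, and 0 changed sign. Genes that passed neither before nor after count as kept, and only the called genes could lose significance. These totals therefore do not measure how stable the calls were. Most genes were named for a small p in these data, which favours a kept sign. Over the 22 alternatives other than the minimum fold, PRSS2 and CST1 in TIS sEV vs Cont sEV passed in each (adjusted p from 8.99e-05 to 0.0121 and to 0.0149), CST1 in TIS sEV vs No sEV in 21 of 22 (adjusted p from 0.00086 to 0.0731, the latter with a constant prior variance). The other 11 calls passed in 7 to 18 of 22. None of these calls passed at a minimum of 1.5-fold. The genes tested differ between filters; otherwise the cause was not tested. Genes called in Cont sEV vs No sEV, 0 in the report, were 7 with no filter on low values, 1 with TPM of at least 5 in at least 3 libraries and 1 with both lowest-weight libraries left out. Genes called in TIS sEV vs No sEV, 1 in the report, were 9 with no filter, 0 with a constant prior variance, 2 with only the 6 libraries compared, 0 at 1.5-fold and 2 with both lowest-weight libraries left out. Genes called in TIS sEV vs Cont sEV, 13 in the report, were 2 with a constant prior variance, 3 with only the 6 libraries compared, 0 at 1.5-fold and 3 with both lowest-weight libraries left out. Genes differing among the 3 groups, 3 in the report, were 13 with no filter, 11 with TPM of at least 5, 6 after quantile normalization and 6 with mitochondrially encoded genes left out. The overlap of 1 gene was 6 with no filter, 0 with a constant prior variance and 0 at 1.5-fold. Lists moved in Cont sEV vs No sEV, 10 in the report, were 2 with an estimated correlation and 2 by fry. In TIS sEV vs No sEV, 7 in the report, they were 14 with no filter, 0 with an estimated correlation and 5 by fry. Those 5 did not include any list that camera moved down there. In TIS sEV vs Cont sEV, 9 in the report, they were 0 with an estimated correlation and 2 by fry. The mitochondrial, YAP/TAZ and glycolysis lists did not pass there (fry, adjusted p = 0.0803, 0.0907 and 0.162). Nor did the immediate early, migration and ribosomal protein lists (fry, adjusted p = 0.0514, 0.185 and 0.814). Leaving out 1 library gave 0 to 1, 1 to 2 and 2 to 13 genes in Cont sEV vs No sEV, TIS sEV vs No sEV and TIS sEV vs Cont sEV, 2 to 4 genes in the F test, an overlap of 1 to 2, and 6 to 10, 5 to 10 and 6 to 10 lists. After quantile normalization camera's direction for the ribosomal protein list reversed in TIS sEV vs No sEV, with a median still below 0, at -0.0045 (adjusted p = 0.722), and in TIS sEV vs Cont sEV, with a median of 0.0193 (adjusted p = 0.0025). In the latter the median was 0.00445 with both lowest-weight libraries left out (adjusted p = 0.457). The lists of TIS sEV vs No sEV were 2 up and 5 down as deposited, 1 up and 5 down after median-of-ratios scaling and 4 up and 2 down after quantile normalization. Those of TIS sEV vs Cont sEV were 6 up and 3 down as deposited, 5 up and 4 down after median-of-ratios scaling and 7 up and 2 down after quantile normalization, and those of Cont sEV vs No sEV were 4 up and 6 down as deposited and 5 up and 4 down after quantile normalization. Of the 13 genes of TIS sEV vs Cont sEV, 10 remained after median-of-ratios scaling and 12 after quantile normalization. With the replicate number as a block, 9 genes passed in TIS sEV vs Cont sEV, 0 higher and 9 lower, and 10, 8 and 9 lists moved. Deviations of same-numbered libraries from their group means correlated by -0.048 to 0.079, and 2 of 9 libraries correlated best with their own number. No strong shared deviation by number was therefore seen, which does not show whether same-numbered samples were handled together. Over scaling and other settings that kept all libraries or left out the pair of lowest weight, 47 medians of called lists changed by over 1.5 times or in sign, 35 of them keeping their call; the median over all genes in TIS sEV vs No sEV was 0.03 as deposited and 0.00125 after median-of-ratios scaling. Depth is unknown, so its limit on low genes was not assessed.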

Other observations

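The tests of the cystatin, mitochondrial and G1/S patterns below, and the readings of the counts of other splits, were written after related values had been seen. In the heat shock list, which did not move between TIS sEV and No sEV (camera, adjusted p = 0.120), 17 of 23 genes were higher, 0 passed over all genes and 4 passed adjusted over the list alone, among them DNAJB4 at 23.3 ± 0.505 against 18.9 ± 1.58 TPM (SD, n = 3) and HSPA1A at 145 ± 4.002 against 128 ± 7.84 TPM. Of the 31-mers of HSPA1A transcripts 73.6% also occur in HSPA1B, so the split between them is uncertain. CD44, a hyaluronan receptor, was at 504 ± 12.8 against 445 ± 14.8 TPM (adjusted p = 0.271), and THBS1, thrombospondin 1, at 119 ± 1.45 against 107 ± 0.366 TPM (adjusted p = 0.271). In TIS sEV vs Cont sEV the extracellular matrix list did not move (adjusted p = 0.549), 0 of its 31 genes passed over all genes, and 5 passed adjusted over the list alone, 2 higher and 3 lower, with FN1, fibronectin, at 113 ± 7.43 against 135 ± 10.9 TPM.

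CST1, CST2 and CST4 were lower with TIS sEV than with Cont sEV, CST2 without passing the test. A move of reads to other cystatin genes was argued against: the summed TPM of 14 cystatin genes changed by -453.6, from 1979 ± 8.99 with Cont sEV to 1525 ± 42.4 with TIS sEV. GC content or length bias as the whole cause was argued against too, since CST1 had a log2 fold change of -0.46 with those trends removed, against -0.47 before. Whether CST4 and CST2 only follow CST1 through shared reads cannot be told apart, because the TPM values do not show how reads were assigned: 40.4% of the 31-mers of CST4 transcripts also occur in CST1, while of those of CST2 9.33% occur in CST1 and 17.7% in CST4, a weaker ground. An effect of TIS sEV on these genes stays open and untested.

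Mitochondrially encoded mRNAs were lower with TIS sEV than with Cont sEV. The difference of group means, 0.678 percentage points, was 0.966 times the range within the Cont sEV group, so variation between libraries may account for it. A lower level of the whole respiratory chain was argued against, since the median log2 fold change of its nuclear-encoded genes was 0.0152. An effect of the vesicles on mitochondrial transcripts stays open and untested.

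The G1/S list was lower with Cont sEV than with No sEV and higher with TIS sEV than with Cont sEV. The mitochondrial share rescaling other genes was argued against, since the median in TIS sEV vs Cont sEV was 0.0721 with mitochondrially encoded genes left out, against 0.0828 before. With GC and length trends removed the median was 0.0548. That step also removes each library's mean offset, and the median over all genes in TIS sEV vs Cont sEV was 0.0203. A part played by GC or length bias therefore cannot be told apart from a shift of scale. A shift of the Cont sEV libraries alone cannot be told apart from a pair of opposite effects, because the median in TIS sEV vs No sEV was 0.0346 and that list did not pass (camera, adjusted p = 0.664). Opposite signs are also what the shared Cont sEV libraries give by chance.

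Other splits of the libraries were counted for each number of calls. In the F test, 5 of 100 splits, the real one included, called at least 3 genes, and the highest of the others called 3, so chance was not excluded. Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In TIS sEV vs Cont sEV the real split called 13 genes and moved 9 lists, against at most 2 genes and 5 lists in other splits, and was the 1 split with as many of each. In TIS sEV vs No sEV it called 1 gene and moved 7 lists, against at most 2 and 5, with 3 splits calling as many genes and 1 moving as many lists. In Cont sEV vs No sEV it called 0 genes and moved 10 lists, against at most 2 and 4, with 10 splits calling as many genes and 1 moving as many lists.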
